A study of Sus scrofa with 28 samples.

How the data were processed

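ATAC-seq uses a transposase that cuts open chromatin and inserts sequencing adapters, and the tagged fragments are sequenced. Here it was applied to liver of female Zlotnicka White pigs, a Polish native breed, of 180 days that were slaughtered at about 100 kg. Per the labels' protocols, liver pieces were kept in hepatocyte medium, digested with Accutase, strained, slowly frozen and made into libraries with a TruePrep kit. The labels give 28 libraries in 4 groups of 7, high or low fat content combined with a number, 200 or 600, whose meaning they do not state. The fat groups stand under a tag named shear force, which does not name fat of the liver. Library titles run through the same 14 numbers in the 200 and the 600 set, so a 200 and a 600 library with the same title number, fat group and replicate number were taken as 2 libraries of 1 animal. The labels do not name the animals. This pairing was checked on the peak numbers, whose deviations from the fat-group means correlated across the 14 pairs (Pearson r = 0.971, permutation p = 1e-05, the smallest that 100000 resamples can give). A second check used 770 regions listed in exactly 1 of the 200 and exactly 1 of the 600 libraries. In 398 of them both libraries had the same fat group and number, against 226 expected from the margins. Of the 6 libraries of the 600 set with at least 5 such regions, however, 3 matched best with their own number. Between 22.6% and 94.0% of the peaks of a 600 library lay in a region with a 200 peak of the same animal. The pairing thus stays an assumption. High and low fat animals with the same number share only that number. All 200 libraries carry one sequencing lane tag and all 600 libraries another, so the label and the lane cannot be told apart.

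The submitters' processing notes name FastQC, BWA, SAMtools, Picard and Genrich with the pig build Sscrofa11.1. They give no versions or roles in the sources used here. The deposited table is one peak list per library, 84192 peaks on 19 chromosomes, and it holds no read counts. Its columns, per the file headers, are the peak's position, a name, a score, a signal value, a p-value column, the summit and the library. The signal value as deposited was never negative and ranged from 400 upward, and it is the area of the peak as the peak caller gives it. The deposited score equalled 1000 times the signal divided by the width, rounded and capped at 1000, in 99.9988% of the peaks, with 0 peaks off by more than 1. It was at the cap in 78.1% of them and never below 800. The deposited p-value column reached 7880.9, so it holds −log10 p, the highest within the peak, and it was 2.83 at the lowest. Peak names carry running numbers with gaps, so called peaks had been removed before the list was made; the listed share of the numbered peaks was at most 3.04% to 52.6% per library. The rule for that removal is not given in the sources used here. A peak list of this kind says where a library passed the caller's limits. An unlisted region can be closed, thinly sequenced or removed by that rule, and widths and areas move with the depth and fragment sizes of the library. Sequencing depth is unknown, so no confidence interval or detection floor from counts is given, and signal and −log10 p, which are the authors' own values per peak, were used to describe, rank and filter peaks, within a library or over the libraries of a label, to set library medians side by side and to follow single sites over libraries. Such values of different libraries also carry their unknown depth.

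Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The plan allowed for read counts, normalized values or peak lists per group, while the file held lists per library. Overlap of the lists with a minimum of 1 bp was kept as planned, and a test of presence was added. Peaks of all libraries in a comparison that overlapped by 1 bp or more were chained into regions. Regions listed in at least 3 libraries were tested with Fisher's exact test, two-sided, on the number of libraries that listed them, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 7 libraries against 7 the smallest p is 0.000583, with 5 against none it is 0.0210 and with 4 against none 0.0699. For both labels together a region counted once per animal, in either of its libraries. The 600 and 200 libraries were compared over 14 against 14, and again within animals by an exact sign test, whose smallest p over 14 animals is 0.000122. The difference of the fat effect between labels was tested by exact permutation of the fat groups over the animals' 600 minus 200 presence. Simulated lists held 200 planted regions, listed with a probability of 0.95 in one group and 0.05 in the other. These probabilities were the same for every library of a group, whatever its peak number. Real libraries with few peaks, down to 39, could hardly list so many of them. The recovered shares below thus overstate what the real lists could give. Past the adjusted threshold, 47.5% were recovered over the 7465 regions of the 200 libraries and 48.0% over the 3404 of the 600 libraries. The share was 49.0% over the 7883 of both labels and 98.0% over the 8592 of the 600 against 200 comparison. For the difference of the fat effect, planted regions had opposite fat effects in the 200 and 600 libraries, and 71.5% were recovered. This last share does not describe a fat effect in only the 200 or only the 600 libraries. With probabilities of 0.7 and 0.1 the shares were 0%, 0%, 0%, 30.0% and 0%, so at 7 against 7 only near-complete differences shared by many regions could pass. No single region could, since p = 0.000583 over 7465 regions (Fisher's exact test) needs at least 88 regions at 7 against 0. The number is 40 for the 600 libraries, 92 for both labels and 101 for the difference of the fat effect, and the planted 200 regions exceed each.

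Library measures (log10 peak number, the shares near gene ends, outside genes and only in that library, median width and median −log10 p) were compared by exact permutation tests of means over all 3432 divisions of 7 against 7, by permutation tests with 100000 resamples for 14 against 14, and by exact sign-flip permutation within animals. All are two-sided. Families held 12 tests for fat, 6 for the label and 6 for the difference. Errors are standard deviations over libraries. Animals are the replicates for fat, and the libraries of an animal for the label.

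Genes came from the RefSeq table of the same build, 28073 genes on the chromosomes of the peak list, 19484 of them protein-coding. A further 2298 genes on unplaced sequence were left out. The table gives no strand, so the planned promoter window around start sites was replaced by a window of 1000 bp around either annotated end of a gene, which takes in start and end sites alike. Exons were not used here. A peak was located by its centre and named by the nearest gene end. The share of peaks near gene ends was set against the mean of 20 random rotations of all peaks along their chromosomes. Of 222 list members, 3 (AGPAT2, KRT7 and HBA) matched no protein-coding symbol or synonym and were left out. Each of the 16 lists was compared with all protein-coding genes by Fisher's exact test, two-sided, adjusted over the lists. The planned set test over a fitted model was not run without counts. In its place, the end-peak genes of the 7 libraries of a fat group were summed, and a list's share of that sum was compared between fat groups by exact permutation of the libraries. Libraries with many peaks weigh most in such a sum. Peak strength near gene ends was compared with that of other peaks within each library by 100000 permutations of the peaks, which are not replicates, and across libraries by an exact sign-flip test.

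Named regions follow the fixed rule, except that some genes it selects are not reported here. Where at least 10 regions passed, the 15 with the smallest p per direction that had a gene symbol were named; otherwise it was the 10 with the smallest p per direction, named as not passing. From the peak lists came the 15 strongest peaks per label with 1 peak per gene, ranked by −log10 p. From every gene list came the counts, 2 to 4 leading members and those without any peak. Genes without a symbol were counted. Alternatives were other overlaps, no minimum number of libraries, peaks above the median strength of all peaks of the label or in its top decile, autosomes only, the replicate block, each library left out, windows of 500, 2500 and 5000 bp, other ways to locate a peak, ends of protein-coding genes only and the middle 90% of widths. Chosen after the data were seen were libraries with at least 1000 peaks, their 1000 strongest peaks, list members with a peak in at least 3 libraries, and genes in place of regions. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.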

Results

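The liver libraries compare pigs of high and low fat content, the question the series title names, in 4 groups of 7 libraries. The number of listed peaks is the only measure of yield. In the 200 set it was 17652, 320, 6288, 1610, 1137, 205 and 11943 for high fat replicates 1 to 7, and 8221, 196, 635, 2467, 617, 4208 and 6691 for low fat replicates 1 to 7. In the 600 set it was 4455, 68, 1336, 190, 142, 39 and 6453 for high fat and 3332, 101, 141, 526, 119, 1325 and 3775 for low fat. High fat replicates 1, 3 and 7 and low fat replicates 1, 6 and 7 thus carried most of the listed chromatin in both sets. The 2 libraries taken as those of 1 animal rose and fell together. This is the correlation on which the assumed pairing was checked, so it is no separate finding about animals. Deviations of log10 peaks from the fat-group means gave Pearson r = 0.971 and Spearman rho = 0.987 over 14 animals. The permutation p was 1e-05 for each, the smallest that 100000 resamples give, and the adjusted p 7e-05 over 7 relations. Without the 2 animals farthest from the median r was 0.977.

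**Figure D1:**
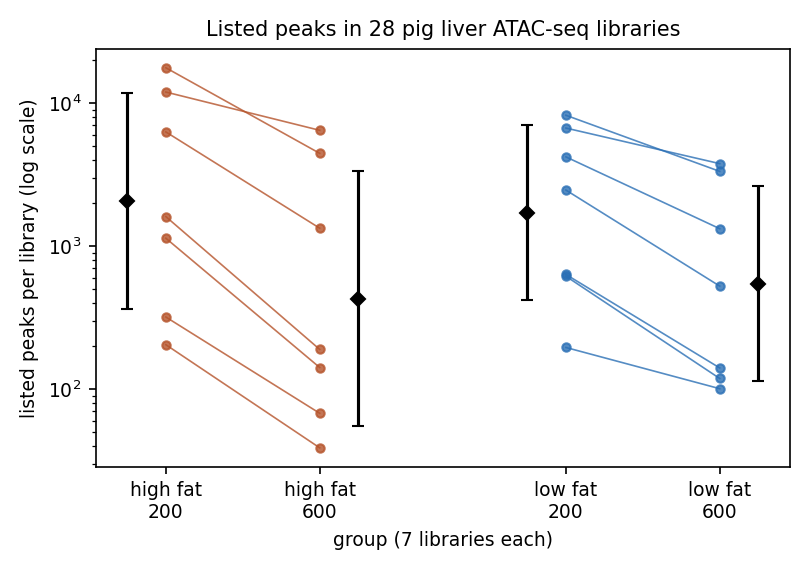
Listed peaks per library (vertical axis, logarithmic) in the 4 groups of 7 libraries (horizontal axis), with a line joining the 200 and the 600 library of each animal and black diamonds for the geometric mean with 1 SD of log10 peaks. The numbers run from 39 to 17652, and the 600 library lies below the 200 library in 14 of 14 animals.

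Open chromatin lay at gene ends far more often than position alone would give. In the 200 libraries 42.2% ± 19.7 (SD, n = 14) of the peaks were within 1000 bp of an annotated gene end, against 4.16% for rotated positions. The share was above that level in 14 of 14 libraries (mean difference 38.1 percentage points ± 19.7, exact sign-flip permutation p = 0.000122, two-sided). In the 600 libraries the share was 45.5% ± 25.9 (n = 14) against 3.94%. It was above in 13 of 14 (difference 41.6 points ± 25.6, exact p = 0.000366 by the same test). The exception was low fat replicate 2, with 1.98% of its 101 peaks near a gene end. Of the recurrent gene-end regions, that of TLE4, a transcriptional corepressor (chromosome 1, 232354790 to 232357221), was listed in 23 of 28 libraries. So were those of SP4, a transcription factor (chromosome 9, 90335793 to 90337922), and ZBTB20, a zinc finger repressor active in liver (chromosome 13, 144854656 to 144856778). HINT3 and PGRMC2 followed with 22, while 21 libraries listed the gene ends of the chaperone genes HSPA13 and HSPD1 as well as CDCA2, COQ10B, PPP2R5A, UBXN4, PCF11 and TPR. Beside the leptin receptor gene, the end of LEPROT, the leptin receptor overlapping transcript (chromosome 6, 146986544 to 146988122), was listed in 19.

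All libraries together gave 29392 regions, of which 17576 (59.8%) came from a single library. High fat 200 replicate 1 alone gave 7007 of them and high fat 200 replicate 3 gave 4296. Single-library regions lay near a gene end in 16.4% of cases and regions of at least 14 libraries in 73.9% (346 of 468). The share was lower again among the most recurrent, 42.4% (25 of 59) for regions of at least 20 libraries, and none of the 9 regions in all 28 libraries was near a gene end. The strongest of these was on chromosome 4 from 53952623 to 53954548, outside genes and 626970 bp from the nearest gene end, with a median deposited −log10 p of 706 (138.7 to 7880.9 over the libraries). Others lay on chromosome 9 from 4699774 to 4702440 (median 373) and on X from 22066775 to 22069793 (median 236). Another was on chromosome 15 from 126761542 to 126763024, 50527 bp from DOCK10, a guanine nucleotide exchange factor (median 35.4). SPOCK3 on chromosome 14 (median 17.1) and PDE4D on chromosome 16 (median 9.62) held 1 each.

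Ranked by −log10 p with 1 peak per gene, the strongest named peaks of the 200 set were those nearest to DOCK10 (72.6), ROPN1L (55.2), SPOCK3 (33.8), PIGG (29.6) and PDE4D (13.7), where each value is the deposited −log10 p of 1 library. Among those that followed were KIRREL3 (12.8), GRM7 (12.6), SLC25A46 (11.8), LEPROT (11.5), DNAH7 (11.2), HINT3 (11.0), GMPS (10.9), PDIA4 (10.9) and TLE4 (10.4). In the 600 set they were nearest to ROPN1L (160.4), DOCK10 (92.3), PIGG (64.0), SPOCK3 (23.99) and PDE4D (12.1). Among those that followed were DGCR6L (11.2), MROH9 (11.13), PGRMC2 (8.67), TLE4 (8.66), CEP57 (8.38), FER (8.28), PPA2 (8.22), HSPD1 (8.14) and SP4 (8.13). LEPROT, HINT3, PDIA4 and TLE4 had these peaks within 1000 bp of a gene end, while those of DOCK10, ROPN1L, SPOCK3, PIGG and PDE4D lay 15690 bp or farther away in the 200 set.

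**Figure D2:**
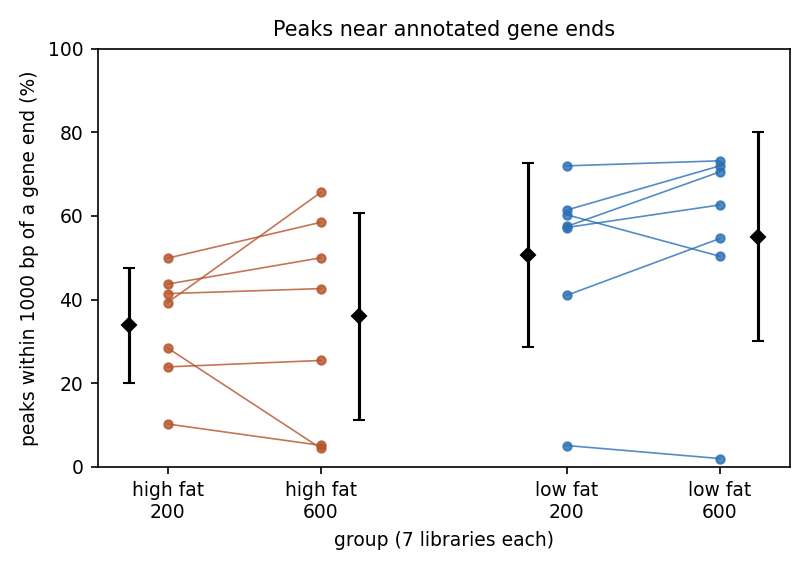
Share of peaks within 1000 bp of a gene end (vertical axis, percent) in the 4 groups of 7 libraries (horizontal axis), with a line joining the 2 libraries of each animal and black diamonds for the mean with 1 SD. High fat libraries averaged 33.8% and low fat libraries 50.6% in the 200 set, and the groups overlap.

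With each library counted alike, peaks at gene ends did not differ detectably in strength from the rest across libraries. Some libraries had very few peaks near gene ends, so their medians are weak. High fat 600 replicate 6 and low fat 600 replicate 2 had 2 each, high fat 600 replicate 2 had 3 and low fat 200 replicate 2 had 10. The median −log10 p near gene ends minus that of other peaks averaged −0.0489 ± 0.5999 (SD, n = 14) in the 200 set (exact sign-flip permutation p = 0.767, two-sided) and −0.119 ± 0.616 (n = 14) in the 600 set (p = 0.495, same test). Within libraries the adjusted permutation test passed in 8 of 14 of the 200 set, 5 with stronger and 3 with weaker gene-end peaks, and the 5 all had at least 6288 peaks. In the 600 set 7 passed, 4 stronger and 3 weaker, and the 4 had at least 3332 peaks.

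Of 16 gene lists, 2 differed from all protein-coding genes in the share of members with an end peak, the clock genes upward and the endothelial and stellate markers downward. Of 19484 protein-coding genes, 9163 (47.0%) had a peak within 1000 bp of an end in at least 1 library. The circadian clock list stood above that share, with 13 of 14 members (92.9%, Fisher's exact test, adjusted p = 0.00455 over 16 lists). It was led by ARNTL, the core activator, in 14 of 28 libraries, NR1D2 in 13 and PER3 in 11. Endothelial and stellate cell markers stood below it, with 0 of 13 (exact adjusted p = 0.00455). PECAM1, KDR, LYVE1, CLEC4G, DCN, COL3A1, RELN and LRAT had no peak in or near the gene at all. Both calls ended with a window of 5000 bp (exact adjusted p = 0.0654 for each) and with the top decile of peaks by strength (0.667 and 0.716). The endothelial and stellate call also ended with a window of 2500 bp (adjusted exact p = 0.0529) and when a member needed a peak in 3 libraries (0.0750). The 47.0% counts gene models without a symbol, whereas list members were chosen by symbol. Genes with a symbol had a higher share on each of the 19 chromosomes, such as 54.9% against 53.0% on chromosome 16 and 53.8% against 39.5% on chromosome 9. Upward differences of the lists would thus be smaller against such genes.

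Lists of fat, sterol and glucose metabolism lay above 47.0% without passing, while pig fatness candidate genes lay below it. The 47.0% is itself lowered by gene models without a symbol, and the direction of several lists depended on the setting. In the top decile of peaks the difference from all genes turned for lipogenesis (−4.73 percentage points), triglyceride synthesis (−5.14) and lipoproteins (−11.4), and that of glucose signalling turned with windows of 2500 bp (−0.721) and 5000 bp (−0.378) and when a member needed a peak in 3 libraries (−2.80). De novo lipogenesis had 11 of 15 members with an end peak (73.3%, exact adjusted p = 0.148). They were led by THRSP, a thyroid-responsive lipogenic gene, in 10 libraries, ELOVL6, a fatty acid elongase, in 7 and ACLY, the ATP citrate lyase, in 5. FASN, the fatty acid synthase, had none at an end, and ACACB and ME1 had none anywhere. Cholesterol and bile acid genes had 11 of 15 (73.3%, exact adjusted p = 0.148). Peaks were at HMGCS1, an enzyme of sterol synthesis, in 16 libraries and SQLE in 11. CYP7A1, the rate-limiting enzyme of bile acid synthesis, had none at an end and CYP8B1 none anywhere. Lipoprotein genes had 12 of 18 (66.7%, exact adjusted p = 0.184). TM6SF2 had one in 6 libraries, and APOA2, APOE and APOH had no peak. Fatty acid oxidation and ketogenesis had 10 of 15 (66.7%, exact adjusted p = 0.283). Leading were ACADM, the medium-chain acyl-CoA dehydrogenase, in 15 libraries and PDK4 in 11, and PPARA, ECI1 and SLC25A20 without any. Triglyceride synthesis and lipid droplets had 10 of 16 (62.5%, exact adjusted p = 0.362). The droplet coat gene PLIN2 had one in 9 libraries and ABHD5 in 7, while PLIN4, DGAT2, GPAM and CIDEC had none anywhere. Glucose and insulin signalling had 8 of 15 (53.3%, exact adjusted p = 0.797). The gluconeogenic gene FBP1 was open in 9 libraries and IRS2 and FOXO1 in 6 each, while G6PC had no peak. Pig fatness candidate genes had 6 of 15 (40.0%, exact adjusted p = 0.658). The adiponectin receptor genes ADIPOR1 and ADIPOR2 led with 19 and 8 libraries, and LEPR, PPARG, MC4R, FABP3, FABP4, FABP5, LEP, FGF21 and ADIPOQ had no peak.

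Hepatocyte transcription factors had 12 of 15 members with an end peak (80.0%, exact adjusted p = 0.0670), a direction that turned in the top decile (−11.4 points). Only with the middle 90% of widths did the list pass (exact adjusted p = 0.0370). NR5A2 had an end peak in 10 libraries and ESRRA and FOXA1 in 9 each. Hepatocyte secretory and metabolic genes had 10 of 16 (62.5%, exact adjusted p = 0.362). HPX led with 11 libraries, before TTR and FGG with 8 each and ALB with 7, and ASGR1, ASGR2 and CYP3A29 had no peak. Immediate early and stress genes, which can respond to handling of tissue, had 12 of 15 (80.0%, exact adjusted p = 0.0670). All 12 recurred in at least 3 libraries, HSPA8 in 19, JUND in 15 and EGR1 in 12. The list passed when a member needed a peak in 3 libraries (exact adjusted p = 0.00120), with peaks above the label's median strength (0.00831) and with the top decile (0.000134). It also passed with a window of 500 bp (exact adjusted p = 0.0271) and the middle 90% of widths (0.0370). With 2500 bp (0.0529), 5000 bp (0.0654), any overlap (0.0624) or peaks located by the summit (0.0670) it did not. Among markers of other cells, Kupffer cell and macrophage genes had 3 of 12 (exact adjusted p = 0.247). CD14 had one in 6 libraries, and CD163, CD68, ADGRE1, VSIG4, CLEC4F, C1QA, C1QB and C1QC had no peak. Cholangiocyte markers had 0 of 6 (unadjusted p = 0.0329, adjusted p = 0.105, Fisher's exact test), and KRT19, EPCAM, SOX9, CFTR and SPP1 had no peak anywhere. Lymphocyte markers had 3 of 11 (exact adjusted p = 0.314). CD3D, NKG7 and CCL5 had one in 1 library each, and CD3E, CD2, CD79A, CD79B, MS4A1 and CD8A had none. Erythroid markers had 1 of 8 (exact adjusted p = 0.148), GATA1 in 2 libraries, with HBB, ALAS2, HBM and AHSP lacking any.

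**Figure D3:**
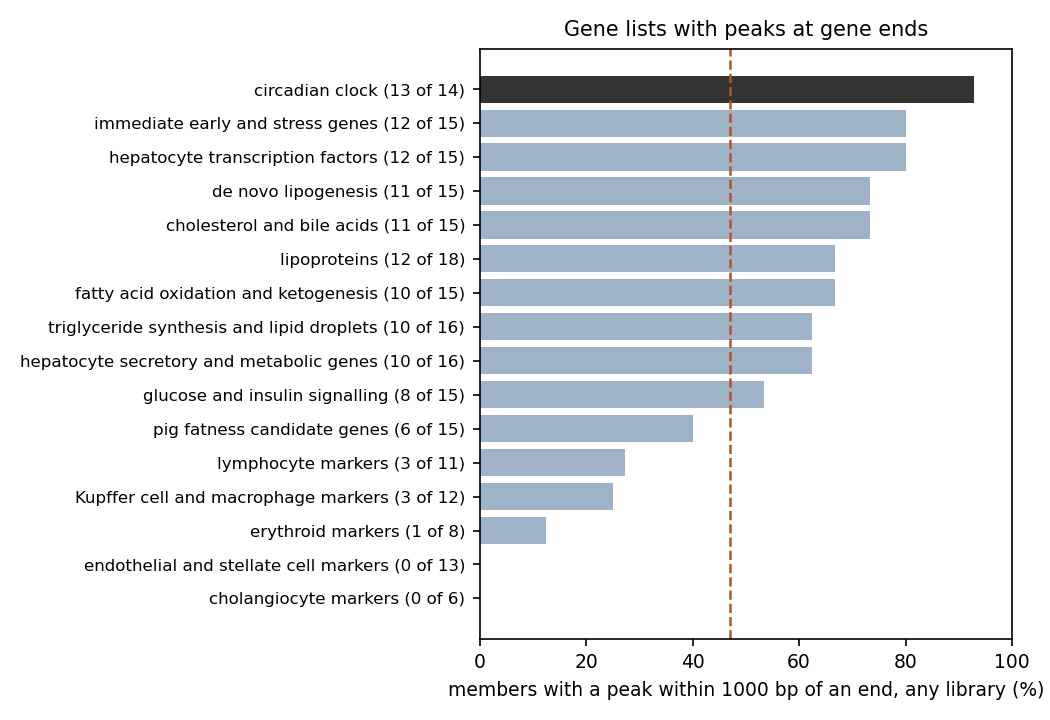
Share of measured members with a peak within 1000 bp of an end in any library (horizontal axis, percent) for the 16 gene lists (vertical axis). Dark colour marks lists with adjusted p below 0.05 and the dashed line is the 47.0% of all protein-coding genes; clock genes reach 92.9% and the endothelial and stellate list, without a visible bar, 0%.

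Livers of pigs labelled with high and low fat content were compared first in the 200 libraries, and no region passed the adjusted threshold. At 7 against 7 libraries a single region could not have passed, since at least 88 regions listed in all libraries of one group and in none of the other would be needed. Of 28566 regions, 17564 (61.5%) were listed only in high fat libraries, 2007 (7.03%) only in low fat libraries and 8995 (31.5%) in both. Of the first, 88.9%, and of the second 95.2%, came from 1 library. The direction turned among the 7465 regions tested, of which 2308 were in more high fat and 3033 in more low fat libraries. At least 4 of 7 high fat libraries listed 619 of them and at least 4 of 7 low fat libraries 1685. Among these 7465, 0 passed the adjusted threshold by Fisher's exact test and 1 had an unadjusted p below 0.05. This compares with 373 expected at that level if p-values were continuous. The unadjusted count ranged from 1 to 18 with a library left out, the most without high fat replicates 7 (18) and 1 (15) and low fat replicate 2 (14), and from 0 to 35 over the other alternatives. That 1 region, on chromosome 5 from 39886199 to 39887730 and 91709 bp from the nearest gene end, was listed in 5 of 7 high fat and 0 of 7 low fat libraries (exact p = 0.0210, adjusted p = 1). Close by, the region from 39893110 to 39894847 was listed in 11 of the 600 and 0 of the 200 libraries. Listing on this stretch thus also moved with the label. Regions at the gene ends of SNX4, a sorting nexin (chromosome 13, 134823856 to 134824576), and SLBP, the histone mRNA stem-loop binding gene (chromosome 8, 818100 to 818817), were not past the threshold. Together with regions nearest to SLC25A46 and inside GRK1, they were listed in 4 of 7 high and 0 of 7 low fat libraries (exact p = 0.0699, adjusted p = 1). The SLC25A46 region, on chromosome 2 from 115563664 to 115563960, also lay close to one that moved with the label. That one, from 115570040 to 115570574, was listed in 10 of the 200 and 0 of the 600 libraries. A region nearest to OSBPL8 was in 6 against 2 (exact p = 0.103). Those of SH3TC1, HSCB, MAP2K5 and NUP160, and one outside genes 6989 bp from JUND, were in 3 against 0 (exact p = 0.192). None of them passed.

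Regions more often listed in low fat libraries did not pass either. The ends of GPD2, the mitochondrial glycerol-3-phosphate dehydrogenase (chromosome 15, 63592833 to 63593800), BCKDHB, a subunit of branched-chain keto acid dehydrogenase (chromosome 1, 86017036 to 86018013), and MOGAT1, a monoacylglycerol acyltransferase (chromosome 15, 124567996 to 124569362), were listed in 2 of 7 high and 6 of 7 low fat libraries (Fisher's exact p = 0.103, adjusted p = 1 for each). The same numbers held at the ends of CNKSR3, GTDC1, EEPD1, NFKBIZ and ISOC1, 1020 bp from the nearest end of ZNF672 and 29211 bp inside NEMP2. Taken gene by gene, 0 of 5191 genes with end peaks in at least 3 libraries passed and 0 had an unadjusted p below 0.05 by Fisher's exact test. Of the 219 list genes, 0 passed adjusted over the list alone, and the smallest unadjusted p was 0.192 (Fisher's exact test). DGAT1, which makes triglyceride, had that p, with 3 high and 0 low fat libraries. Summed over libraries, where those with many peaks weigh most, the triglyceride synthesis list took 0.116% of the genes with end peaks in high fat and 0.0536% in low fat libraries (10 members against 4, exact permutation p = 0.00991, n = 7 each). It did not pass the adjustment over 16 lists (adjusted exact p = 0.159), and the other lists had adjusted p of 0.554 or more.

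Library measures of the 200 set did not separate the fat groups after adjustment. Peak numbers had geometric means of 2063 and 1716 (ratio 1.202, exact permutation p = 0.829, two-sided), and without high fat replicate 1 the ratio turned to 0.841. Peaks near gene ends made up 33.8% ± 13.7 in high and 50.6% ± 22.1 in low fat libraries (SD, n = 7 each, exact permutation p = 0.112, adjusted p = 0.339 over 12 tests). Peaks found in no other library of the set made up 31.7% ± 20.5 and 10.1% ± 7.98 (exact permutation p = 0.0146, adjusted p = 0.175, n = 7 each).

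In the 600 libraries no region passed the adjusted threshold either, where at least 40 regions at 7 against 0 would be needed. Of 8863 regions 4131 (46.6%) were listed only in high fat, 506 (5.71%) only in low fat and 4226 (47.7%) in both. Of the first, 86.9%, and of the second 89.1%, came from 1 library. Of 3404 tested, 921 were in more high fat and 1336 in more low fat libraries, and 109 and 461 were in at least 4 of 7 libraries of the group. Of these 3404, 0 passed the adjusted threshold and 0 had an unadjusted p below 0.05 by Fisher's exact test, and the smallest p was 0.0699. The unadjusted count ranged from 0 to 10 with a library left out, the most without low fat replicate 2 (10) and high fat replicates 7 (9) and 1 (8), and from 0 to 2 over the other alternatives. Regions at RPS13, a ribosomal protein gene (chromosome 2, 42030078 to 42031144), CDK16, RIC8B, MIPEP and ARF2 were in 3 of 7 high and 0 of 7 low fat libraries (exact p = 0.192). The same numbers held 1234 bp from the nearest end of ZC3H4 and 25964 bp from that of AGO4. One nearest to OSBPL8 was in 7 against 5 (exact p = 0.462), and those of C2CD3 and RUSC2 were in 3 against 1 (p = 0.559). More often listed in low fat were regions of FER, a tyrosine kinase gene (chromosome 2, 113773471 to 113775515), STT3B, MRPS28, ZNF622, SSX2IP and AZI2, in 2 of 7 high and 6 of 7 low fat libraries (exact p = 0.103). A region nearest to ROPN1L was in 1 against 5 (exact p = 0.103), and those of NMRK1, METTL25 and DMXL1 were in 3 against 6 (p = 0.266). All had exact adjusted p = 1. Gene by gene, 0 of 2705 passed and 0 had an unadjusted p below 0.05 by Fisher's exact test. Likewise 0 of the 219 list genes passed adjusted over the list alone (smallest unadjusted p = 0.462, Fisher's exact test). Every list had exact adjusted p = 1 between the fat groups of this set.

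Geometric mean peak numbers of the 600 set were 431 and 548 (ratio 0.786, exact permutation p = 0.802, n = 7 each), and the ratio turned to 1.17 without high fat replicate 6. The share of peaks near gene ends was 36.0% ± 24.8 in high and 55.1% ± 25.01 in low fat libraries (exact permutation p = 0.167, adjusted p = 0.401, n = 7 each). Peaks in no other library of the set made up 21.4% ± 23.4 and 5.78% ± 6.76 (exact permutation p = 0.0787, adjusted p = 0.339). High fat replicate 3 alone had 69.7%, and the difference of 15.6 points ranged from 7.62 to 19.1 with a library left out.

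With both labels joined by animal, 29392 regions fell into 18141 (61.7%) listed only in high fat, 1952 (6.64%) only in low fat and 9299 (31.6%) in both. Of the first, 88.7%, and of the second 96.2%, came from 1 animal. Of 7883 tested, 2446 were in more high fat and 3110 in more low fat animals, and 680 and 1774 were in at least 4 of 7 animals of the group. At least 92 regions at 7 against 0 would be needed to pass. Of these 7883, 0 passed by Fisher's exact test, and 1, the region on chromosome 5 from 39886199, had an unadjusted p below 0.05 (5 of 7 against 0 of 7 animals, p = 0.0210). That count ranged from 1 to 18 with an animal left out and from 0 to 2 over the other alternatives. Regions of SLC25A46, SNX4, SLBP and GRK1 kept 4 of 7 high and 0 of 7 low fat animals, and others nearest to MROH9, PCDH1, a protocadherin gene, and NKX6-2 had the same numbers (exact p = 0.0699). OSBPL8 had 6 against 2 (exact p = 0.103), and HSCB and MAP2K5 had 3 against 0 (p = 0.192). On the low fat side CNKSR3, GTDC1, GPD2, EEPD1, ISOC1, MOGAT1, NEMP2 and YAF2 had 2 against 6 and ROPN1L 1 against 5 (exact p = 0.103), and PDPR 0 against 3 (p = 0.192). All had exact adjusted p = 1.

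The 600 libraries differed from the 200 libraries in a small set of regions, nearly all outside genes. Of 8592 regions tested over 14 against 14 libraries, 42 passed Fisher's exact test, 41 more often listed in the 200 set and 1 in the 600 set, and 387 had an unadjusted p below 0.05 (384 and 3). Among all 8592, 7172 were in more 200 libraries and 570 in more 600 libraries. The 200 lists were also longer in 14 of 14 animals. The direction of these regions thus cannot be told apart from list length. The 42 became 81 with 50% reciprocal overlap and 21 with the top decile of peaks by strength. Regions nearest to MROH9 (chromosome 9, 63418518 to 63418746), PMP22, a myelin gene (chromosome 12, 58676929 to 58677220), and ZNF484 (chromosome 3, 41852149 to 41853429) were listed in 14 of 14 of the 200 and 0 of 14 of the 600 libraries (exact adjusted p = 5.35e-05). Those nearest to PIGG (chromosome 8, 19073 to 19498), JMJD4 (chromosome 2, 50672141 to 50672668) and GFRAL (chromosome 7, 25809158 to 25809445) were in 13 and 0 (exact adjusted p = 0.000459). One nearest to SLC25A46 (chromosome 2, 115570040 to 115570574) was in 10 and 0 (exact adjusted p = 0.0312). The 1 region more often listed in the 600 set, on chromosome 5 from 39893110 to 39894847, 84695 bp from the nearest gene end, was in 11 of 14 of the 600 and 0 of 14 of the 200 libraries (exact adjusted p = 0.00883). Tested within animals by the exact sign test, which cannot go below p = 0.000122, 0 of the 8592 regions passed and 201 had an unadjusted p below 0.05, 197 of them more often in the 200 set. None passed, either, in the animals with at least 1000 peaks in both libraries. So few libraries could pass only with very many fully separated regions, so this says little.

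Of the 41, none was near a gene end, 1 was elsewhere in a gene and 40 were outside genes, while 58.6% of all tested regions were near gene ends. A region could pass in this direction only if most 200 libraries listed it, those with few peaks among them, so the 41 are no random draw of the tested regions and the shares were not compared by a test. They had a median width of 619 bp, 27 were in none of the 600 libraries, and 29 fell into 5 clusters. The clusters were on chromosome 9 from 63230976 to 63480216 (14 regions), chromosome 5 from 39995988 to 40179611 (5), chromosome 6 from 38750556 to 38834120 (4) and from 55804834 to 56746318 (3), and chromosome 8 from 14804 to 19498 (3). Named regions that did not pass in favour of the 200 set were those of PTPRO (0 of 14 and 9 of 14, exact adjusted p = 0.0977), GRM7 (1 and 10, 0.209), SH2D3C, VPS36 and OSBPL8 (0 and 8, 0.259), and FAM160B1 and TWSG1 (0 and 7, 0.566). In favour of the 600 set none with a gene symbol passed. DGCR6L had 11 of 14 and 4 of 14 libraries, MAGEE2 9 and 3, ROPN1L 6 and 1, TRPM3 4 and 0, OSBPL8 12 and 7 and DDX11 5 and 1 (exact adjusted p = 0.772). The same adjusted p was that of MROH9, TEX14, ACADL, CHL1, NREP and ESR1, each with 3 and 0, while DIRC2, CARF and EMCN had 4 and 1 (exact adjusted p = 0.911).

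As whole libraries, the 600 set held fewer and wider peaks. Peak numbers were 0.258 times those of the 200 set (permutation p = 0.0395, adjusted p = 0.0791 over 6 tests). Within animals the drop passed, in 14 of 14 (exact sign-flip permutation p = 0.000122, adjusted p = 0.000366). Median widths were 1001 bp ± 78.3 against 509 bp ± 39.3 (SD, n = 14 each, permutation test, adjusted p = 6e-05, higher in 14 of 14 animals). Median −log10 p was 3.87 ± 0.389 against 4.25 ± 0.324 (permutation p = 0.00876, adjusted p = 0.0263, within animals adjusted p = 0.00195, lower in 13 of 14). The call ended among peaks above each label's median strength (difference 0.000278) and in the top decile, where the direction turned (1.25), both being selections by −log10 p itself. The share near gene ends was 45.5% ± 25.9 against 42.2% ± 19.7 (permutation p = 0.710). Peaks in no other library of the set made up 13.6% ± 18.4 against 20.9% ± 18.7 (permutation test, adjusted p = 0.477), and only within the assumed animals did this pass (exact adjusted p = 0.0157, lower in 11 of 14). Within the 600 set the share near gene ends rose with log10 peak number (Pearson r = 0.675 and Spearman rho = 0.662, n = 14, permutation test, adjusted p = 0.0328 and 0.0419 over 7 relations, r = 0.665 without the 2 farthest libraries). Inside its fat groups r was 0.754 for high and 0.652 for low fat (exact permutation, adjusted p = 0.0787 each). In the 200 set r was 0.540 and rho 0.433 (permutation test, adjusted p = 0.0787 and 0.219), and r fell to 0.148 without the 2 farthest libraries.

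Whether the fat effect differed between labels was tested last. Of 8592 regions 0 passed the exact permutation test after adjustment and 3 had an unadjusted p below 0.05 (5 to 39 with an animal left out, 0 to 5 over the other alternatives). At least 101 regions with complete separation would be needed to pass. Regions of FBXL4, an F-box gene of mitochondria (chromosome 1, 65934999 to 65936299), and NAPA, a membrane fusion gene (chromosome 6, 53274939 to 53276092), were each in 2 high and 5 low fat libraries of the 200 set and in 2 and 0 of the 600 set (exact p = 0.0210, adjusted p = 1). The third was the region on chromosome 5 from 39886199 (5 and 0, then 0 and 0). In the same direction as FBXL4, GPD2 and EEPD1 had 2 and 6, then 2 and 2. ZSWIM4 had 2 and 5, then 2 and 1, and NAIF1, RHOB, SS18L2 and PCYOX1L had 2 and 4, then 2 and 0 (exact p = 0.0699). In the other direction ZNF622 had 6 and 6, then 2 and 6, and KCNMB3 had 6 and 5, then 2 and 5. SLC25A46, SNX4, SLBP and GRK1 had 4 and 0, then 0 and 0, and NKAIN1 had 4 and 1, then 0 and 1 (exact p = 0.0699). AGPAT5 had 7 and 5, then 2 and 4, OSBPL8 6 and 2, then 0 and 0 (exact p = 0.103), and SH3TC1 3 and 0, then 0 and 1 (p = 0.122). Median −log10 p changed from the 200 to the 600 library by −0.228 ± 0.332 in high fat animals and by −0.541 ± 0.168 in low fat animals (exact permutation p = 0.0379, adjusted p = 0.227 over 6 tests, n = 7 each).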

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

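The tests of animal sample and fat group on peak numbers were chosen only after the peak numbers were seen, while the counts over random divisions of the libraries were planned. Low fat replicate 2 stood far from the other low fat animals. In its 600 library 1.98% of the peaks were near a gene end, against 50.4% in the nearest other library, and 90.1% were outside genes, against 34.0%. In its 200 library 78.6% of the peaks were outside genes, against 32.9% in the nearest. Low fat 600 replicate 5 had 19.3% of its peaks in no other 600 library, against 7.92%. Each of these was singled out because its gap to the nearest library was large beside the range of the group by Dixon's criterion, which chance meets in about 1 of 20 groups; it was met in 4 of 28 groups. High fat 600 replicates 2 and 6 had similarly low gene-end shares, 4.41% and 5.13%, within a group of wider spread. High fat replicate 3 did not meet the criterion either. It had 69.5% of its 200 peaks and 69.7% of its 600 peaks in no other library of the set. A difference between the fat groups was noted once: median −log10 p changed from the 200 to the 600 library by −0.228 ± 0.332 in high fat and −0.541 ± 0.168 in low fat animals, a difference of 0.313 (exact permutation p = 0.0379, n = 7 each) that did not pass over 6 tests (adjusted p = 0.227).

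Peak numbers spread from 205 to 17652 in the high fat 200 group alone. Fat group accounted for 0.392% of the variance of log10 peak numbers in the 200 set, which argues against it as the source of that spread. Each set carries a single lane tag, so lanes were not tested within a set. Libraries taken as those of 1 animal had a Spearman rho of 0.987. A common source in each animal's sample would give this, but the pairing itself was checked on the same correlation, and by single regions 3 of 6 libraries of the 600 set matched best with their own number. The state of each sample thus stays open. What differed between the samples, by handling or by the animal itself, was not measured, and the depth of each library is unknown.

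Random divisions of the same libraries, 100 per comparison with the real one included, put the region counts in context. For fat in the 200 set 64 gave at least as many regions at an unadjusted p below 0.05 as the real 1, and the highest other gave 2302. For both labels joined it was 71 (real 1, highest other 958) and for the difference of the fat effect between labels 82 (real 3, highest other 244), so chance cannot be excluded for these comparisons. In the 600 set the real count was 0, which all 100 divisions reach by construction (highest other 937), so nothing follows from it there. The division with 2302 regions parted libraries by yield. It had a peak-number ratio of 7.02 between its sides, against 1.202 for fat. The highest other division had a ratio of 11.8 in the 600 set and 9.91 for the difference of the fat effect. For both labels joined it was 2.89, with 80 of 100 divisions below it. A structure of the samples by peak number is thus possible, but region counts were not tested against peak numbers over the divisions. For the 600 against the 200 libraries, 2 of 100 divisions gave as many regions as the real 42 at the adjusted threshold, so chance as the source of the count was excluded at 0.05. The highest other gave 1383 with a peak-number ratio of 4.51, and 97 of 100 divisions had a lower ratio. The real division itself had a ratio of 3.87, so it also parted libraries by yield. This count therefore cannot set the label apart from peak number. Among 100 divisions that swapped labels only within animals, the real one alone reached 42 and the highest other gave 23. Swaps mix the shorter and longer lists of the animals, so the same limit holds there.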

How the results depend on the processing

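Alternatives added after the data were seen were the libraries with at least 1000 peaks, their 1000 strongest peaks, a list peak in 3 or more libraries and genes in place of regions; the rest were planned. Region counts by fat (200, 600 and both labels) and for the difference of the fat effect were 0 past the adjusted threshold under every alternative run. With 7 against 7 at least 88, 40, 92 and 101 regions of complete separation would be needed to pass, so these counts say little about stability. At an unadjusted exact p below 0.05 the counts moved. In the 200 set the count of 1 was 23 in libraries with at least 1000 peaks, 35 with their 1000 strongest peaks, 3 with 50% reciprocal overlap and 0 with the top decile or the replicate block, and 1 to 18 with a library left out (18 without high fat replicate 7, 15 without 1, 14 without low fat replicate 2). The 600 set gave 0 to 2 and, with a library left out, 0 to 10 (10 without low fat replicate 2, 9 and 8 without high fat replicates 7 and 1), both labels 0 to 2 and 1 to 18, and the difference of the fat effect, 3 in the report, 0 to 5 and 5 to 39 (39 without low fat replicate 2). A group of 6 has other attainable p-values, which enters these counts. High and low fat animals share only a number, so that block pairs nothing. The 42 regions of the 600 against 200 comparison became 81 with 50% reciprocal overlap, 21 with the top decile of peaks and 0 with the replicate block over animals. With an animal left out they ranged from 33 to 43. They were 0 in the animals with at least 1000 peaks in both libraries, high fat 1, 3 and 7 and low fat 1, 6 and 7. With the 1000 strongest peaks of those libraries they were 0 as well. So few libraries could pass only with very many fully separated regions, so these zeros say little. The sign test of the block cannot go below 0.000122, which lowers what can pass. The cause of the other changes was not tested. The ratio of high to low fat peak numbers turned to 0.949 above the label's median strength and 0.972 in libraries with at least 1000 peaks in the 200 set (0.837 to 1.77 with a library left out) and to 1.32 in such libraries of the 600 set (0.5005 to 1.17). It turned without high fat 200 replicates 1 (0.841), 3 (0.998) or 7 (0.897), low fat 200 replicate 2 (0.837), high fat 600 replicates 2 (1.07) or 6 (1.17) and low fat 600 replicates 1 (1.06) or 7 (1.08). The 600 to 200 ratio passed with the block (0.258) and in animals with at least 1000 peaks in both libraries (0.357), and ranged from 0.243 to 0.274. Libraries with at least 1000 peaks were chosen by the measure itself, so their ratios of peak numbers say nothing about its stability. Between labels, the difference of the gene-end share turned to −0.841 points in the top decile, and that of median −log10 p to 0.000278 above the median strength and 1.25 in the top decile. Strength near gene ends turned to 0.0115 in the 200 set with the middle 90% of widths and, in the 600 set, to 0.0417 with 500 bp, 0.0293 with 5000 bp, 0.0253 with any overlap and 0.0751 with the middle 90% of widths. Gene lists past the threshold, 2 in the report, were 1 in the top decile, 1 with 2500 bp, 0 with 5000 bp (Fisher's exact test) and 4 with the middle 90% of widths. The immediate early and stress list joined the 2 above the label's median strength and with 500 bp, and was the 1 in the top decile. With a peak in 3 or more libraries it passed while the endothelial and stellate list did not. In the top decile the difference from all genes turned for lipogenesis (−4.73 points), triglyceride synthesis (−5.14), lipoproteins (−11.4) and hepatocyte transcription factors (−11.4), and that of glucose signalling turned with 2500 bp (−0.721), 5000 bp (−0.378) and a peak in 3 or more libraries (−2.80). Of 144 list shares compared, 125 kept direction and side of the threshold, 6 passed only in the alternative, 6 no longer passed and 7 turned, and 191 of 1752 values of single list genes moved beyond their binomial interval. Count-based tools, their normalizations, pseudocounts and quantile normalization were not run because the lists hold no counts; peaks on assembled chromosomes only, and protein-coding ends for the lists, changed nothing by construction. Depth, which is unknown, limits what an unlisted region can mean.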

Other observations

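Gene families in this part, the tests of the recurrent strong sites and those of the chromosomes were all chosen after values had been seen. Among 16315 genes with a symbol, 33.4% had an end peak in at least 3 libraries, and 11 of 18 families differed from that share (Fisher's exact test, adjusted over the families). Above it, SR and hnRNP splicing factors reached 24 of 30 (80.0%, exact adjusted p = 1.96e-06), with HNRNPA1, HNRNPA3, HNRNPC and HNRNPUL1 in 13 libraries each. Heat shock proteins and their DNAJ co-chaperones reached 40 of 69 (58.0%, exact adjusted p = 7.98e-05), with HSPA13, HSPD1 and HSPE1 in 21 libraries, and translation initiation factors 24 of 39 (61.5%, adjusted p = 0.00105), with EIF4G2 in 16. Complex I genes of mitochondria had 25 of 47 (53.2%, exact adjusted p = 0.0104) and RAB GTPases 29 of 59 (49.2%, adjusted p = 0.0206).

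Below it, none of 35 keratin and 36 HOX genes had an end peak in 3 libraries (adjusted p = 3.7e-06 each, Fisher's exact test), and collagens had 1 of 42 (COL5A2, adjusted p = 4.84e-06). Potassium channel genes had 6 of 92 (exact adjusted p = 1.97e-08), GPR receptors 8 of 71 (adjusted p = 6.91e-05) and zinc finger genes 65 of 254 (25.6%, adjusted p = 0.0131). Cytochromes P450, at 6 of 37 (16.2%), did not pass (exact adjusted p = 0.0518), with CYP2R1, a vitamin D hydroxylase, and CYP51, of sterol synthesis, in 11 libraries each. Solute carriers, ribosomal, mitochondrial ribosomal and proteasome genes, UBE2 enzymes and nuclear receptors, at 28.6% to 45.5%, did not differ past the threshold (exact adjusted p = 0.0715 to 0.669).

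The 9 regions listed in all 28 libraries, none near a gene end, are a pattern to follow up. If they gathered reads whatever the quality of a library, their −log10 p would fall as the peak number rises. It fell at 7 of 9 in the 200 set and at 5 of 9 in the 600 set, and with 5 sites this explanation stays open. Of the listed signal of a library, the sites held 2.21% (high fat replicate 1) to 72.3% (high fat replicate 2) in the 200 set. In the 600 set it was 22.5% (high fat replicate 7) to 98.2% (low fat replicate 3). Such a share rises by itself where few other peaks are listed, so it does not decide. If the 9 sites were open chromatin like that of recurrent gene ends, their −log10 p would rise with peak number as it did there (median Spearman 0.883 over 479 regions of the 200 set). The median over the 9 sites was −0.235 (−0.745 to 0.780), a difference of −1.12. Sites listed in all 28 libraries had to pass even in libraries with few peaks, which by itself works against a rise with peak number. The gene-end regions met no such demand, so this comparison cannot decide, and no explanation from the study's groups was tested. The 9 sites may be sequence present in more copies than the assembly holds, which would need the genome, not used here.

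On gene-dense chromosomes a lower share of the genes had an end peak. The share ran from 33.5% on chromosome 12, with 18.2 protein-coding genes per Mb, to 62.9% on chromosome 10, with 5.80 (Spearman −0.584 over 19 chromosomes, permutation p = 0.0101; Pearson −0.662, and −0.502 without the 2 farthest). Gene models without a symbol were argued against as the whole cause, since the Spearman stayed at −0.546 (p = 0.0172) without them. Short genes were weighed by removing the share expected from gene length, which left −0.468 (permutation p = 0.0445), against them as the whole cause but near the threshold; this replaced a test by length class whose values, −0.316, −0.672 and −0.409 from short to long genes, had been seen and were mixed. Base composition may account for the rest and stays open with no genome used here, and no biological explanation was tested.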
